A study of Mus musculus with 5 samples.

How the data were processed

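Polyadenylated RNA from sorted mouse hair follicle stem cells was sequenced in 5 samples, 2 Control and 3 PRC1 i2KO, and the authors deposited 1 table with an expected count and a TPM value for each of 30840 features in each sample. Per the labels' protocols, 50 ng of RNA with an integrity number above 8 entered a Universal Plus mRNA-Seq library preparation, and libraries were read on an Illumina HiSeq instrument. The submitters' processing notes name STAR 2.7.9a, RSEM 1.3.3, DESeq2 1.38.2 and the genome build mm39, without their roles. The deposited expected counts are estimates, of which 60.4% were not whole numbers, and they were rounded for the tests. The deposited TPM values are scaled for transcript length and summed to between 999962.6 and 999977.5 per sample. Whether the counting used strand is not given in the sources used here. Feature identifiers were matched to GENCODE M21 of assembly GRCm38, where 99.97% were present, 97.8% with the same version. Because the notes name another build, that annotation was used only for gene names, types and overlaps, and no coordinates are given. In the table, 26 symbols occurred more than once and 207 features had no count in any library.

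Samples were grouped by genotype from their labels, and their numbers are those of the sample titles. The titles number the controls 2 and 3, while the sample descriptions number the same controls 1 and 2 and give the PRC1 i2KO samples the numbers of their titles. A block by title therefore sets Control 2 and 3 beside PRC1 i2KO 2 and 3, and a block by description sets them beside PRC1 i2KO 1 and 2. The library alone in its block, PRC1 i2KO 1 by title and PRC1 i2KO 3 by description, then adds nothing to the group contrast. Such fits leave fewer residual degrees of freedom than the fit with group only. The labels do not state that samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. PRC1 i2KO differs from Control by the K15-CrePR1 transgene as well as by the deletion it induces. Totals ranged from 11626006 to 43307694 counts, so 1 count stood for between 0.0203 and 0.0793 CPM. Counting intervals (95%) and the floor of 3 counts over both controls, equal to 0.0485 CPM, cover counting error only.

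Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, quasi-likelihood F test, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled library sizes. Of 22181 genes tested, 15041 were protein-coding. Fold changes are PRC1 i2KO over Control, and the ± beside a log2 fold change is its standard error. A gene with no control count is given as at least the fold over the floor, and one with 1 to 3 control counts as a ratio with its counting interval. The test was tried on simulated counts for the same 22181 genes, libraries and group sizes with 200 changed genes. It recovered 11.9%, 44.8% and 75.8% of the 2-fold, 4-fold and 8-fold changes, and 5.38% of its calls fell on unchanged genes. DESeq2 1.42.0 recovered 19.4%, 59.7% and 84.8% with 31.9% of its calls on unchanged genes, and limma-voom (limma 3.58.1) 8.96%, 43.3% and 69.7% with 15.6%. Counts were simulated in a single run, each gene at the trended dispersion, with changed genes of at least 1 CPM, up or down at random. DESeq2 ran there on the filtered genes and in the data on unfiltered counts (30631 features). These shares may therefore not hold for the data.

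The design, the alternatives and 31 gene lists were set before the data were examined. The lists came from textbook knowledge of Polycomb, the hair follicle and skin cell types and hold 927 entries, of which 833 are in the table. They cover PRC1 subunits, PRC2 subunits, H2AK119 deubiquitinases, Hox genes, developmental transcription factors, cyclin-dependent kinase inhibitors, bulge identity, quiescence and BMP signalling, hair germ and anagen onset, Hedgehog, WNT, FGF and TGF-β ligands, DNA replication, mitosis, p53 targets, inner root sheath and hair shaft, interfollicular epidermis, upper follicle and sebaceous gland, Merkel cell, melanocyte, fibroblast and dermal papilla, immune cell, endothelial, mural and muscle, Schwann cell, adipocyte, basal keratinocyte, simple keratins, interferon, immediate early and heat shock, mitochondrially encoded and sex-linked genes. Each was tested with camera against all other genes, first with its preset correlation of 0.01 and then with a correlation estimated from these 5 libraries, adjusted over the 31 lists. With the preset correlation 10 lists were higher and 1 lower, and with the estimated correlation 0 lists passed, the smallest adjusted p being 0.0724. A higher correlation alone does not account for this loss. The estimates for WNT (-0.0062) and upper follicle genes (0.0071) lay below the preset. Their unadjusted camera p still rose, from 0.000570 to 0.0303 and from 7.32e-09 to 0.00943. What else differs between both forms of the test was not tested. The self-contained test fry called 1 list, the developmental transcription factors. Genes to be named were the targeted genes, the 10 largest changes in each direction among called genes with no overlap between groups, a mean of at least 1 CPM and an established symbol, up to 4 members of each list by adjusted p, and every member of a list with 12 or fewer tested members. Members of these short lists that are not named are covered by the counts and medians of their list. The second part of this rule named 10 genes, of which Hoxd13, Hoxd11, Hoxd10, Dmrt3, Dmrta2, Pitx1, Sim2, Hoxa13 and Gpr50 are given and 1 is not reported here. The other called genes outside the rule were named as well, and these, the 4 lower genes, Hoxa7, Hoxc10, Hoxc12, Zic2, Tbx15, Cd34, Mki67, Dlk1 and the abundant fibroblast transcripts of the closing section were chosen after their values were seen.

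Alternatives were other normalizations (DESeq2's size factors, upper quartile), other filters on low counts, DESeq2, limma-voom, robust dispersion, limma on log2(TPM + 1) and log2(TPM + 0.1), a block for sample numbers, other thresholds, and leaving out each library in turn. Those added after seeing the data left out ribosomal RNA features, kept protein-coding genes only, thinned all libraries to the shallowest total, or tested the lists with no filter. With 2 samples against 3, an exact permutation test of 1 gene cannot give a p below 0.1, so none was used.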

Results

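RNA was sequenced from hair follicle stem cells of adult mouse back skin, with and without induced loss of Polycomb repressive complex 1 (PRC1). This complex attaches ubiquitin to histone H2A (the mark H2AK119ub) through Ring1a (gene Ring1) or Ring1b (gene Rnf2), and the series asks how that mark relates to the quiescence of these cells. All mice lacked Ring1a and carried loxP-flanked Ring1b, and all received 1% RU-486 on the skin daily for 10 days from postnatal day 50. The PRC1 i2KO group (3 samples) also carried K15-CrePR1, a Cre recombinase that RU-486 activates in keratin 15-expressing cells. The Control group (2 samples) did not. At postnatal day 70, cells positive for EpCAM and CD34, high for α6-integrin and negative for Sca1 were sorted, and 50000 of them were used per sample. Total counts were 42916190 in Control 2, 11626006 in Control 3, and 25461650, 43307694 and 34669748 in PRC1 i2KO 1, 2 and 3. Mitochondrial ribosomal RNA took 16.7% and 22.6% of the counts in the controls and 29.7%, 21.4% and 32.0% in the PRC1 i2KO libraries. Spearman correlations of log2 CPM (counts scaled by library size) between libraries lay between 0.891 and 0.930, and no pair of libraries agreed within sampling noise.

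The gene-level values of the targeted genes did not separate the groups in counts. Rnf2 (ENSMUSG00000026484.13) was at 27.7 and 37.5 CPM in the controls and at 39.9, 33.1 and 36.4 CPM in the PRC1 i2KO libraries, a log2 fold change of 0.16 ± 0.25 (SE; edgeR adjusted p = 0.870). In the deposited TPM values, which are scaled for transcript length, every PRC1 i2KO library lay below both controls, with 25.1 and 24.4 TPM in the controls and 16.8, 12.9 and 11.7 TPM in the PRC1 i2KO libraries. The log2 fold change on the log2(TPM + 1) scale was -0.81 and did not pass the limma test (adjusted p = 0.481). The transcript length implied by the ratio of count to TPM was 1.32, 1.83 and 1.86 times the control mean in the PRC1 i2KO libraries, against 0.986 and 1.01 in the controls. Ring1 (ENSMUSG00000024325.8), null by genotype in every mouse, had 92 and 63 counts in the controls and 50, 70 and 116 counts in the PRC1 i2KO libraries (log2 fold change -0.44 ± 0.73, adjusted p = 0.884). Gene-level counts pool deleted and retained exons, so neither gene checks the labels.

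**Figure D1:**
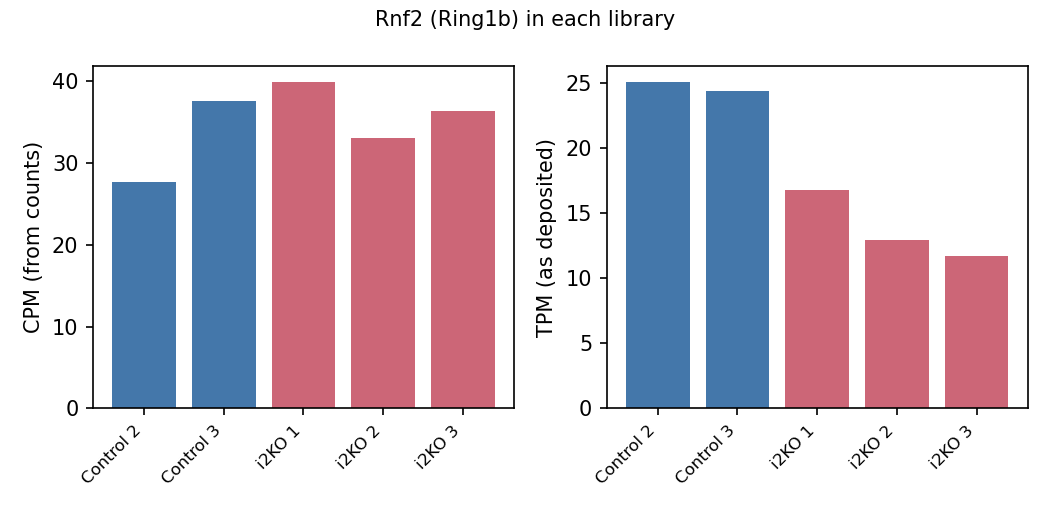
Rnf2 in each library, as CPM computed from the deposited counts (left) and as deposited TPM (right); each bar is 1 library, blue for Control and red for PRC1 i2KO. Counts overlap between the groups, while TPM is 24.4 or more in both controls and 16.8 or less in all 3 PRC1 i2KO libraries.

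Of 22181 genes tested, 28 rose in the PRC1 i2KO libraries (edgeR, adjusted p under 0.05), among them the transcription factor genes Hoxd13, Dmrt3 and Sim2, each with at most 1 count over both controls. All 28 lay higher in each PRC1 i2KO library than in both controls, an order that the test itself favours, that 14.6% of all tested genes showed and that chance gives in 10% of cases. The growth factor gene Igf2 (ENSMUSG00000048583.16) rose from 1.84 ± 0.243 CPM (SD, n = 2) to 245 ± 38.5 CPM (SD, n = 3), a log2 fold change of 7.03 ± 0.28 (SE; edgeR adjusted p = 3.10e-05). Onecut2 (ENSMUSG00000045991.18), a homeodomain transcription factor, rose from 4.93 ± 0.578 to 173 ± 12.4 CPM (log2 fold change 5.12 ± 0.24, adjusted p = 5.97e-05). Hoxd13 (ENSMUSG00000001819.4), a posterior patterning gene, had 1 count over both controls and 32.0 ± 1.92 CPM in PRC1 i2KO, a ratio of 1991 with a 95% counting interval of 357 to 78644 (adjusted p = 0.000168).

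The risen genes are given by what they encode, a grouping made after the calls and not tested for enrichment. Among transcription factor genes, Hoxd10 (324-fold), Hoxd11 (457-fold), Hoxa13, Pitx1, Sim2, Pax2 (30.4-fold), Ebf3 (20.2-fold), Mecom (70.9-fold), Tox2 (89.8-fold), Tcf24 (33.1-fold) and Cux1 (4.65-fold) rose. The folds of Hoxd10, Hoxd11, Mecom and Tox2 are uncertain, as they rest on 6, 4, 8 and 4 counts over both controls. Hoxd11 was at 0.0203 and 0.238 CPM in Control 2 and 3 (log2 fold change 8.84 ± 0.70). Dmrt3 and Dmrta2 had no count in either control, and their levels of 11.0 ± 3.17 and 6.46 ± 0.757 CPM in PRC1 i2KO were at least 221-fold and 136-fold higher than 3 counts over both controls (adjusted p = 0.0154 and 0.0253). Pitx1 and Sim2 had 1 control count each, with ratios of 447 (interval 80.2 to 17643) and 466 (83.6 to 18393), while Hoxa13 had 2, with a ratio of 278 (77.1 to 2299). Timp3, an inhibitor of metalloproteinases, rose from 43.4 ± 5.48 to 241 ± 58.8 CPM (5.57-fold, adjusted p = 0.0107), the secreted matrix protein gene Smoc2 by 6.79-fold, and the small leucine-rich proteoglycans Bgn and Prelp by 19.6-fold and 42.2-fold. Fibroblast markers were higher as a list in the same libraries, with a median log2 fold change of 1.42 (adjusted p = 0.190 with an estimated correlation). Also risen were Gpr50 (443-fold), Trank1 (log2 fold change 5.73), Elfn1 (44.5-fold), Begain (10.8-fold), Cfap298 (7.30-fold), Nptx1 (6.81-fold) and Eva1c (5.29-fold). Gpr50 had 0 counts in Control 2 and 7 in Control 3, so its fold is uncertain (log2 fold change 8.79 ± 1.07). In 17 of the 28 genes the control mean was below 1 CPM, and the smallest log2 fold change was 2.22.

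**Figure D2:**
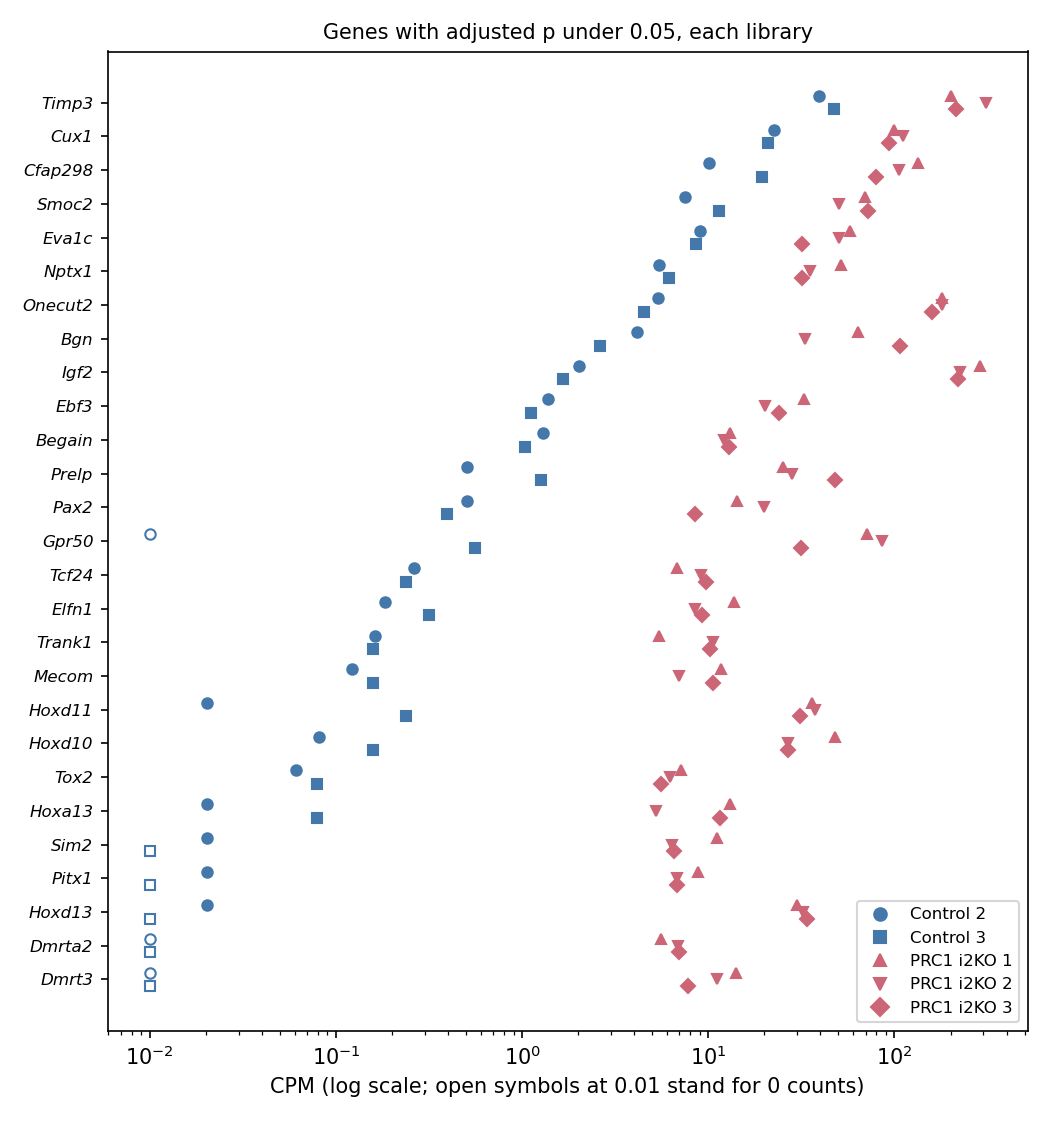
CPM of 27 of the 28 genes with adjusted p under 0.05 in each library, on a log axis, ordered by control mean; each symbol is 1 library, and open symbols at 0.01 stand for 0 counts. Every red PRC1 i2KO symbol lies to the right of both blue control symbols of its gene.

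No gene passed as lower by edgeR, against 778 genes lower and 1647 higher at an unadjusted p under 0.05. Of the other tools, DESeq2 called 754 genes higher and 166 lower, limma-voom 4 and 0, limma on log2(TPM + 1) 7 and 13, and limma on log2(TPM + 0.1) 7 and 1. Under other settings edgeR did call lower genes, with 12 beside 140 higher ones with no filter on low counts, 6 beside 54 among protein-coding genes alone and 4 beside 39 without PRC1 i2KO 2. The 4 lower genes with an adjusted p under 0.10 by edgeR were Pdzrn4 (126 ± 20.1 to 46.5 ± 7.62 CPM, adjusted p = 0.0551), Grik1 (22.3 ± 13.1 to 2.94 ± 0.473 CPM, 0.0679), the transglutaminase gene Tgm5 (608 ± 36.9 to 325 ± 20.3 CPM, 0.0836) and the predicted gene Gm45062 (6.07 ± 3.53 CPM to no count, 0.0522). The count of 28 depended on each library: without Control 2 it was 4, without Control 3 it was 8, and without PRC1 i2KO 1, 2 or 3 it was 8, 43 or 14. In the reference annotation 8 of the 28 genes, among them Igf2, Hoxd10, Hoxd11 and Cux1, overlap a gene on the same strand and 8 others, such as Timp3, overlap only genes on the opposite strand, so the values of these genes are uncertain to the extent that counting split shared reads.

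Across the gene lists fixed before the data were examined, developmental transcription factors had the smallest adjusted p. Of the 79 tested members, 6 rose, Onecut2, Pitx1, Sim2, Dmrta2 and Pax2 among them, and 0 fell, against 36 and 0 adjusted over the list alone, and 43 and 0 at an unadjusted p under 0.05 (DESeq2, 32 and 0; limma-voom, 1 and 0). The list's median log2 fold change was 2.68, and 16 members had no control count. The median was the same with these set to their bound and members of 1 to 3 control counts set to their ratio. A median does not move while such members stay on the same side of it, so this is a weak check. The list's adjusted p by camera was 1.51e-30 with the preset correlation and 0.0724 with an estimated correlation. Of the 79 members, 28 had a control mean of at least 1 CPM. Members silent in control enter the test only when expressed in PRC1 i2KO and can then only be higher, which favours a rise of the list. With no filter, all 120 members in the table were tested, with a median of 2.19 (camera adjusted p = 1.62e-20, preset correlation). That setting does not remove the bias, since members with no control count can still only be higher. The 28 members expressed in control were not tested apart. Zic2, a patterning gene with no control count (5.04 ± 2.46 CPM in PRC1 i2KO, adjusted p = 0.0618), and Tbx15 (0.300 ± 0.137 to 7.68 ± 2.79 CPM, adjusted p = 0.0679) did not pass.

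Among the 35 tested Hox genes, Hoxd13, Hoxd11, Hoxd10 and Hoxa13 rose by edgeR and 0 fell, against 10 and 1 adjusted over the list alone (at an unadjusted p under 0.05, 12 and 1). DESeq2 called 9 higher and 1 lower, limma-voom 0 and 0, and limma on log2(TPM + 1) 3 and 0. The gene lower when adjusted over the list alone was Hoxa7, at 141 ± 12.2 CPM in control and 73.3 ± 6.77 CPM in PRC1 i2KO (edgeR adjusted p over all genes 0.134). The list was higher by camera (adjusted p = 1.45e-09, but adjusted p = 0.190 with an estimated correlation). Its median log2 fold change was 0.20 and its mean 1.77, and on the log2(TPM + 1) scale the median was -0.20 where that of all genes was -0.25. Without Control 2 or 3 the median was 0.46 or 0.31, and without PRC1 i2KO 1 it was 0.013. Hoxc12 (3.54 ± 0.83, adjusted p = 0.182) and Hoxc10, with no control count, did not pass.

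**Figure D3:**
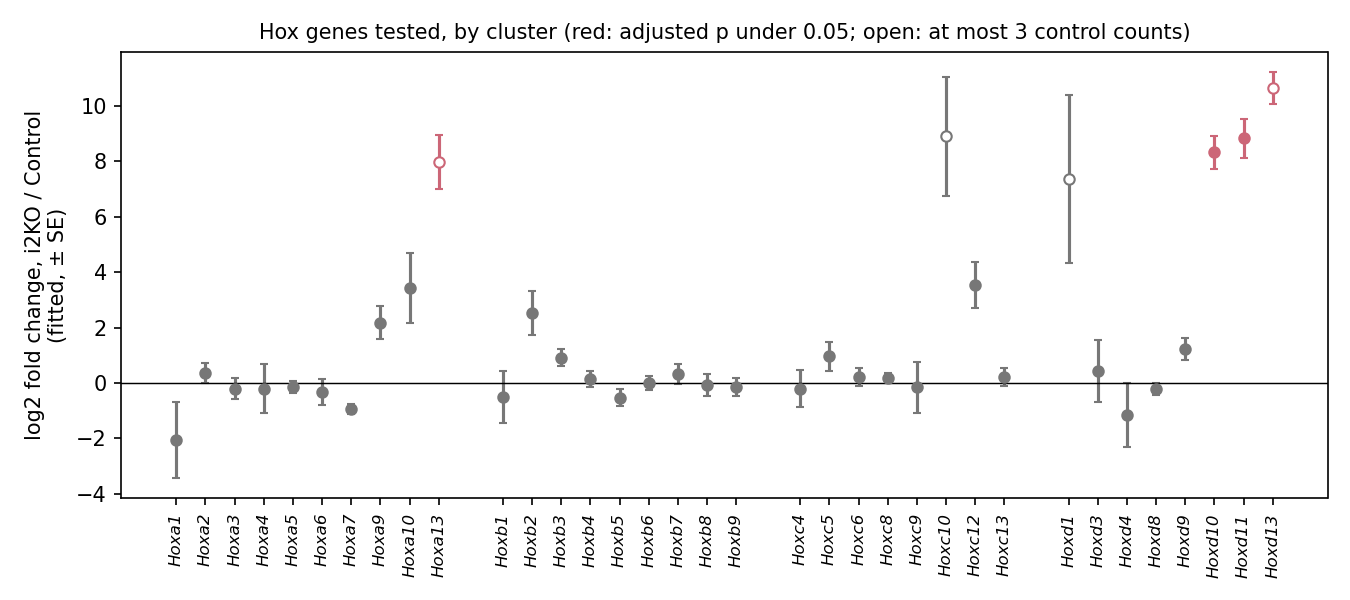
Fitted log2 fold change ± SE of the 35 tested Hox genes, PRC1 i2KO against Control, by cluster and number along the horizontal axis; red points have an adjusted p under 0.05 and open points at most 3 control counts. Hoxd10, Hoxd11, Hoxd13 and Hoxa13 lie at 7.98 or above, while the 27 genes numbered 1 to 9 have a median of -0.06. Hoxc13, which controls express at 37.5 CPM, lies at 0.20.

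Genes of cell division were higher as a list, unevenly between libraries. The 42 mitosis genes had a median log2 fold change of 1.99, with 40 positive (camera adjusted p = 4.48e-12, and adjusted p = 0.470 with an estimated correlation). By edgeR 0 members passed over all genes and 8 rose adjusted over the list alone (at an unadjusted p under 0.05, 19 higher and 0 lower; DESeq2, 9 and 0; limma-voom, 0). The median shift of these genes from the control mean was 1.25, 0.083 and 2.60 in PRC1 i2KO 1, 2 and 3, and the proliferation marker Mki67 was at 13.2 and 34.0 CPM in the controls and at 173, 38.1 and 404 CPM in PRC1 i2KO (adjusted p = 0.240). Mitochondrial ribosomal RNA was likewise higher in PRC1 i2KO 1 and 3, at 29.7% and 32.0% of counts, than in PRC1 i2KO 2, at 21.4%, and the mitochondrially encoded genes shifted by 0.90, 0.41 and 0.81 in PRC1 i2KO 1, 2 and 3. Without PRC1 i2KO 3 the median of the mitosis genes was 1.07. Foxm1, a mitotic transcription factor, had a log2 fold change of 3.12 ± 0.60 (adjusted p = 0.134), Anln one of 3.23 (0.150) and Aurkb one of 5.04 (0.189). Melk had 1 control count and a ratio of 290 (interval 52.1 to 11471, adjusted p = 0.139). The 40 genes of DNA replication had a median of 0.45 (camera adjusted p = 0.0160, and adjusted p = 0.603 with an estimated correlation), with 0 members past edgeR's threshold, also adjusted over the list alone (unadjusted, 7 higher and 0 lower; DESeq2, 2 and 0). That call was lost without Control 2 (adjusted p = 0.175) and without PRC1 i2KO 3 (median 0.19, adjusted p = 0.687), while the median was 0.70 without PRC1 i2KO 2. On the log2(TPM + 1) scale it was 0.011 where that of all genes was -0.25. Rrm2 (log2 fold change 2.37), Mcm5 (1.99) and E2f1 (2.58) had adjusted p between 0.197 and 0.355.

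Cell cycle inhibitors and p53 targets were not called. The 6 tested cyclin-dependent kinase inhibitors (Cdkn1a, Cdkn1b, Cdkn1c, Cdkn2b, Cdkn2c and Cdkn2d) had a median log2 fold change of 0.80 (camera adjusted p = 0.305), or 0.36 without PRC1 i2KO 1, and Cdkn2b, a known Polycomb target, one of 2.47 ± 0.85 (adjusted p = 0.332). The other of the 7 listed inhibitors was not analysed here. The 26 p53 targets had a median of 0.24 (camera adjusted p = 0.125).

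Bulge stem cell genes were slightly lower as a list, and a single member rose. The 36 members had a median log2 fold change of -0.13 (camera adjusted p = 0.0414, and adjusted p = 0.576 with an estimated correlation). Of these, 15 lay lower in every PRC1 i2KO library than in both controls, an order that 15.3% of all tested genes showed. Timp3 rose and 0 fell, against 1 and 2 adjusted over the list alone (unadjusted, 2 and 11; DESeq2, 1 and 2; limma-voom, 1 and 0). The 2 lower members were the BMP antagonist Grem1 (923 to 565 CPM, log2 fold change -0.71 ± 0.16, adjusted p = 0.172) and the quiescence-associated ligand Fgf18 (50.3 to 19.5 CPM, -1.37 ± 0.33, adjusted p = 0.188). Ctgf (833 to 453 CPM, adjusted p = 0.240) and Cd34, the sort marker (402 to 252 CPM, adjusted p = 0.422), did not pass. The list's call was lost with DESeq2's size factors (adjusted p = 0.0524) and without Control 3 (median -0.028, adjusted p = 0.126), PRC1 i2KO 2 (0.0742) or PRC1 i2KO 3 (0.261). The 25 genes of quiescence and BMP signalling had a median of -0.03 and a mean of 0.12 (camera, down, adjusted p = 0.932), and a median between -0.17 and 0.099 when each library was left out in turn. They held Bmp4, at 1.12 CPM in control and 11.1 CPM in PRC1 i2KO (3.26 ± 0.57, adjusted p = 0.0936), as well as Smad9 (-0.62, 0.349) and Bmp7 (0.74, 0.394).

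Genes of the activated hair germ and of WNT signalling were higher as lists. These lists are not independent, since 14 of the 32 hair germ and 8 of the 28 WNT members are also in another list, and Wnt10a is in both. The 32 hair germ and anagen genes had a median log2 fold change of 0.69, with 27 positive (camera adjusted p = 2.10e-07, and adjusted p = 0.190 with an estimated correlation). Cux1 rose and 0 fell, against 7 and 0 adjusted over the list alone (unadjusted, 11 and 0; DESeq2, 8 and 0; limma-voom, 1 and 0). Below the threshold stood Msx1 (2.03, adjusted p = 0.150) and Ccnd2 (0.94, 0.165). Without PRC1 i2KO 3 the median was 0.40. The median shift from the control mean was 0.72, 0.28 and 0.61 in PRC1 i2KO 1, 2 and 3. It was thus lowest in PRC1 i2KO 2, as were the mitosis shift and the mitochondrial ribosomal RNA share among these libraries. The 28 WNT genes had a median of 0.52 (camera adjusted p = 0.00196, and adjusted p = 0.190 with an estimated correlation), with 0 members past edgeR's threshold and 2 higher adjusted over the list alone (unadjusted, 7 and 0; DESeq2, 4 and 0). The median was 0.79 without Control 2. Wnt10a (1.87), the WNT effector Lef1 (1.48), Wnt6 (2.07) and Wnt5a (1.89) had adjusted p between 0.177 and 0.326.

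Markers of other epidermal compartments were higher as lists with no member past edgeR's threshold. The 27 upper follicle and sebaceous gland genes had a median log2 fold change of 1.00 (camera adjusted p = 4.54e-08, and adjusted p = 0.146 with an estimated correlation), with 1 higher adjusted over the list alone (unadjusted, 13 and 0; DESeq2, 5 and 0). That member was Krt17 (150 to 376 CPM, adjusted p = 0.0867), and without PRC1 i2KO 3 the median was 0.66. Among the others were Cst6 (1.98, adjusted p = 0.239), Gata6 (1.89, 0.240) and Far2 (1.84, 0.273). The 40 interfollicular and differentiating epidermis genes had a median of 0.96, with 38 positive (camera adjusted p = 5.69e-08, and adjusted p = 0.470 with an estimated correlation) and 0 adjusted over the list alone (unadjusted, 11 and 1; DESeq2, 6 and 0). Ly6d (1.62), Elovl4 (1.41), Casp14 (1.62) and Krtdap (1.44) had adjusted p between 0.164 and 0.232. The median shift of this list was 1.70 in PRC1 i2KO 2 and 0.13 and 0.32 in PRC1 i2KO 1 and 3, and without PRC1 i2KO 2 its median log2 fold change was 0.26. Basal keratinocyte genes (median -0.03, mean 0.02, camera adjusted p = 0.999) and inner root sheath and hair shaft genes (0.23, 0.999) were not called, with medians of -0.14 to 0.11 and of 0.013 to 0.35 when each library was left out in turn.

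The 14 fibroblast and dermal papilla genes, cells outside the sort gate, had a median log2 fold change of 1.42 (camera adjusted p = 0.000381, and adjusted p = 0.190 with an estimated correlation). By edgeR 0 passed and 7 rose adjusted over the list alone (unadjusted, 7 and 1; DESeq2, 4 and 0). Pdgfra went from 2.80 to 24.6 CPM (3.11 ± 0.45, adjusted p = 0.0502), Col1a1 from 3.17 to 12.9 CPM (2.02, 0.215), Col5a1 had a log2 fold change of 1.55 (0.240) and Vim one of 4.27 (0.287). The 13 mitochondrially encoded genes had a median of 0.71 (camera adjusted p = 9.90e-12, and adjusted p = 0.422 with an estimated correlation), with 0 past edgeR's threshold and 12 higher adjusted over the list alone (unadjusted, 12 and 0; DESeq2, 9 and 0). Examples were mt-Atp6 (0.78 ± 0.17, adjusted p = 0.165), mt-Cytb (0.78, 0.172), mt-Co2 (0.69, 0.177) and mt-Nd4l (0.81, 0.178), and mitochondrial messenger RNA took 4.54% and 4.86% of control counts and 6.20%, 5.11% and 6.43% of PRC1 i2KO counts. Median log2 fold changes of the uncalled marker lists were 0.49 for immune cells (camera adjusted p = 0.305), -0.20 for melanocytes (mean 0.04, 0.477), 0.14 for endothelial, mural and muscle cells (0.999), 0.42 for Schwann cells (0.0874) and 0.90 for adipocytes (0.513). Leaving out each library in turn moved these medians between 0.18 (without PRC1 i2KO 3) and 3.58 (without Control 3) for immune cells, -0.56 and 0.48 for melanocytes, 0.022 and 1.10 for endothelial, mural and muscle cells, and 0.46 and 0.60 for Schwann cells. These medians are partly over different genes. Without Control 2 or 3 the filter let in more members, 19 or 20 immune cell genes against 12 with all libraries. For adipocytes the median was 0.44 without PRC1 i2KO 1.

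**Figure D4:**
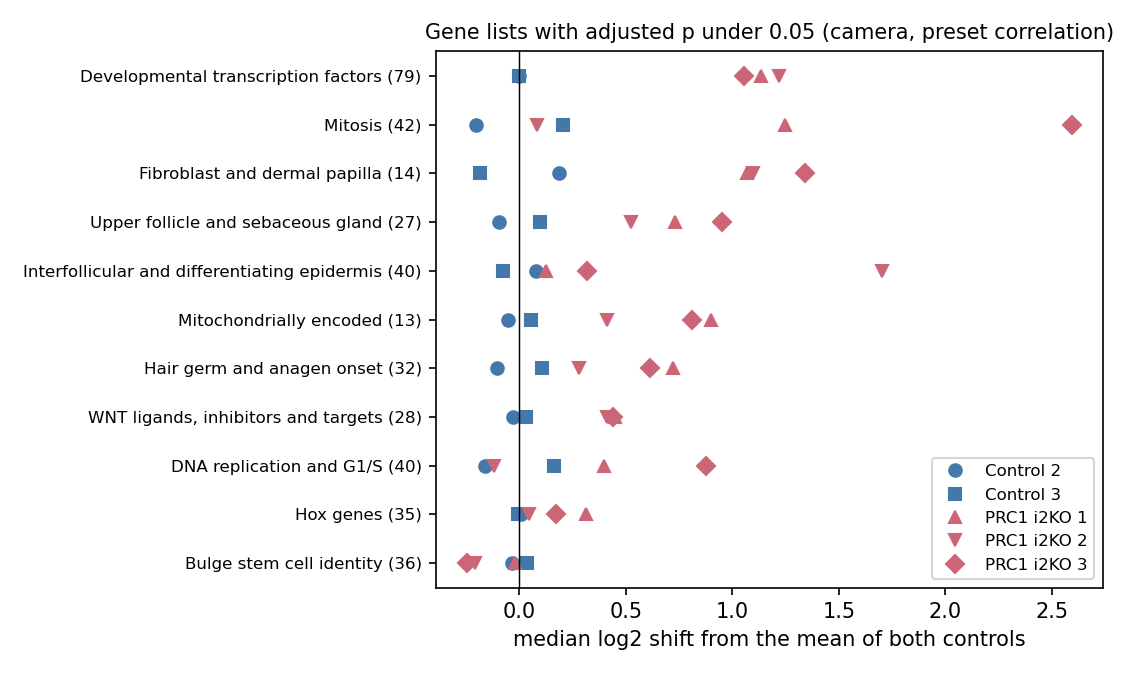
Median over list members of log2(CPM + 0.5) minus the mean of both controls, for each library and each list with an adjusted p under 0.05 by camera with its preset correlation; members tested are in parentheses. Mitosis genes shift by 2.60 in PRC1 i2KO 3 and by 0.083 in PRC1 i2KO 2, while epidermal genes shift most in PRC1 i2KO 2, by 1.70.

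Genes of the Polycomb system itself were not called. The median log2 fold change was 0.14 over 31 PRC1 subunits (camera adjusted p = 0.309), -0.07 over 14 PRC2 subunits (0.305) and 0.05 over 11 deubiquitinases of this mark (0.725). Leaving out each library in turn moved these medians between 0.068 and 0.18, -0.24 and -0.064, and -0.053 and 0.091. The PRC1 subunits nearest the threshold were Bcor (0.86 ± 0.27, adjusted p = 0.284), Bmi1 (0.67, 0.349), Phc1 (1.76, 0.458) and Phc3 (-0.34, 0.486). The other uncalled lists were Hedgehog (0.23, camera adjusted p = 0.522), FGF and TGF-β ligands (0.53, 0.0874), interferon and inflammation (0.48, 0.309) and immediate early and heat shock genes (-0.15, 0.298). Their medians moved between -0.057 and 0.24, 0.26 and 0.91, 0.33 and 0.81, and -0.23 and 0.00066 in the same way.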

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

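The alternatives without ribosomal RNA features, with protein-coding genes only, with thinned libraries and with lists tested on unfiltered counts were chosen after the data were seen. All 28 genes kept a positive fold change under each alternative to the test of genes. All 28 stayed past the threshold with DESeq2's size factors (30 genes called in all), robust dispersion (34), no filter (152), a filter of 1 CPM in 2 libraries (45), DESeq2 (920), no ribosomal RNA features (34), protein-coding genes only (60) and thinning (52), and all 28 met a 2-fold minimum. With upper-quartile scaling 27 of the 28 stayed (29 called), and at a threshold of 0.01 the stricter setting itself left 5. Limma-voom called 4 genes, all among the 28, and limma on log2(TPM + 1) and log2(TPM + 0.1) called 20 (13 lower) and 8 (1 lower), of which 5 each were among the 28. Limma on log2(TPM + 1) with no filter called 0, against 564 higher and 2048 lower at an unadjusted p under 0.05. The cause of these differences was not tested. The median log2 fold change of all genes was -0.12 with upper-quartile scaling and -0.25, -0.31 and -0.11 in these TPM fits. Leaving out each library in turn gave 4 to 43 genes, and of the 28 it kept 4 without Control 2, 6 without Control 3, and 8, 22 and 14 without PRC1 i2KO 1, 2 and 3. With 1 control left, that control was assumed to vary like the other group. The filter then left 23605 genes to test without Control 2 and 24614 without Control 3, against 22181 with all libraries. List medians without a control can therefore cover other members. Lower genes were 12 with no filter, 6 among protein-coding genes, 3 each with the 1 CPM filter and thinning, 2 with upper-quartile scaling, 1 with robust dispersion and 4 without PRC1 i2KO 2. Leaving Rnf2 and Ring1 aside, 90 genes were tracked by name, 27 of the 28 among them, of which each alternative tested 82 to 90, and 0 changed direction where tested, while DESeq2 passed 47 more of them and limma-voom 23 fewer.

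Rnf2 and Ring1 passed no test. Rnf2 turned negative in TPM, at -0.81 on the log2(TPM + 1) scale with and without the filter and at -0.85 on the log2(TPM + 0.1) scale. Leaving out a library moved Rnf2 between -0.040 and 0.41 and Ring1 between -0.99 and 0.43. The causes were not tested.

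With an estimated correlation, in some below the preset, 0 of the 11 called lists kept their call. Leaving out a library gave 9 to 12 called lists, and 9 of the 11 kept their call each time, all but the bulge and DNA replication lists. The bulge list also lost its call with no filter (adjusted p = 0.0521). Relative to the median of all genes, medians in counts, on log2(TPM + 1) and on log2(TPM + 0.1) were 2.68, 1.45 and 3.16 for developmental transcription factors (79 members in counts, 33 in TPM), 1.98, 1.18 and 1.48 for mitosis, 0.95, 0.56 and 0.66 for interfollicular epidermis, 0.68, 0.41 and 0.52 for hair germ, and 0.45, 0.26 and 0.31 for DNA replication. For fibroblasts the first 2 were 1.42 and 0.93. TPM fits held fewer members of each list. Beyond the 11, immune cell genes passed with no filter (camera adjusted p = 0.0194), where 21 members were tested against 12. Without Control 3 the median was 3.58 over 20 immune cell genes and -0.23 over 31 immediate early genes. Without Control 2 it was 0.55 over 12 Schwann cell genes, against 11 tested with all libraries. The adipocyte list had too few tested members without PRC1 i2KO 2 or 3 and gave no value there. Leaving out 1 library turned the sign of the uncalled medians for deubiquitinases, quiescence, Hedgehog, Merkel cells, melanocytes, basal keratinocytes, simple keratins and immediate early genes.

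With title numbers as a block edgeR called 165 genes (25 lower), keeping all 28, and with description numbers 10, all among the 28. Each contrast rests on 2 pairs of libraries. The title block also called 12 lists, the 11 and the Schwann cell list (adjusted p = 0.0368). The labels tie no animal or batch to the 2 shared title numbers. Deviations of same-numbered pairs correlated at 0.167 and 0.0972, others at -0.167 to 0.0773. With 2 controls these are mirrored, so pairing is open.

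In simulated data of this depth and size edgeR recovered 11.9% of 2-fold changes, so a gene not called here is not shown to be unchanged.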

Other observations

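The tests on fibroblast RNA, on the share of mitochondrial and ribosomal RNA and on the libraries with more mitotic RNA were chosen after the result was seen.

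Several genes of cells other than keratinocytes appeared at low levels in the PRC1 i2KO libraries without passing edgeR's threshold. The 9 tested Merkel cell genes split in direction, with a median log2 fold change of -0.43 and a mean of 2.07 (camera, up, adjusted p = 0.148). The median was positive without Control 2 (1.49), Control 3 (2.91), PRC1 i2KO 1 (3.05) or PRC1 i2KO 3 (0.044) and with no filter (2.30). More members were tested without either control (11) and with no filter (15), so these medians are partly over different genes. Adjusted over the list alone, 4 were higher and 1 lower, while over all genes 0 passed (unadjusted, 4 and 2; DESeq2, 3 and 0). The higher ones were the mechanosensitive channel gene Piezo2 (2.95 ± 0.44, adjusted p = 0.0554), Isl1 (no control count, at least 33.3-fold higher, 0.177), Krt8 (ratio 56.9, interval 15.8 to 470, 0.177) and Sox2 (no control count, at least 7.80-fold higher, 0.290). The lower one was the neuropeptide gene Cck, at 22.2 CPM in control and 7.35 CPM in PRC1 i2KO (adjusted p = 0.357). Of the simple epithelial keratins (median 0.28, and -0.012 to 1.15 with each library left out in turn, camera adjusted p = 0.477), Krt8 was higher and Krt19 lower (1.93 to 0.261 CPM, adjusted p = 0.347).

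Among immune genes, the MHC class II genes H2-Eb1 (no control count, at least 46.4-fold higher, adjusted p = 0.141) and H2-Aa (log2 fold change 2.95, adjusted p = 0.240) were higher in every PRC1 i2KO library than in both controls. Ms4a1, a B cell gene, was lower in each (1.94 to 0.575 CPM, adjusted p = 0.513). The groups overlapped in the other 9 of the 12 tested immune genes, which were the class II genes H2-Ab1 and Cd74 and Cd3d, Cd3e, Ptprc, Ccl5, Csf1r, Cd68 and Itgam. Dlk1, an imprinted Notch-related ligand, was at 4.07 CPM in control and 31.9 CPM in PRC1 i2KO (2.93 ± 0.45, adjusted p = 0.0603). The 6 sex-linked genes had a median log2 fold change of -0.22 and a mean of 0.05 (camera adjusted p = 0.544), and a median between -0.46 and -0.019 with each library left out in turn. Xist was at 575 and 10.0 CPM in the controls and at 787, 862 and 7.28 CPM in PRC1 i2KO 1, 2 and 3, and the Y-linked Ddx3y was at 31.8, 35.3, 17.7, 16.7 and 47.0 CPM in the same order. The labels give no sex. High Xist beside Ddx3y in Control 2, PRC1 i2KO 1 and PRC1 i2KO 2 is what a pool of males and females would give, which was not tested. Xist thus differed strongly between libraries within both groups, and the comparison does not account for sex.

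All 28 called genes were higher in PRC1 i2KO, and some, such as Bgn and Prelp, are also expressed by fibroblasts. RNA from dermal fibroblasts, which the EpCAM gate should remove, would bring their abundant transcripts, yet Col1a1, Col1a2, Col3a1, Sparc, Dcn and Lum together changed by -36.9 CPM against 1310 CPM for the called genes, a ratio of -0.0282. Without Sparc, which control cells express at 397 and 310 CPM, the other 5 rose by 12.7 CPM in sum (ratio 0.00973), and 11 of the 14 fibroblast list genes had a control mean of at least 1 CPM. Against a larger share of mitochondrial and ribosomal RNA, the counts left beside it differed between libraries by at most 0.36 (log2), where the smallest log2 fold change of the 28 was 2.22. As for the lower depth of Control 3, 28 of 28 lay above both controls in every PRC1 i2KO library after thinning. That order was close to fixed in advance, since the 28 were called for large rises. The deeper Control 2 also lay below every PRC1 i2KO library in all 28. Loss of PRC1, which the design names, and an effect of the K15-CrePR1 transgene itself were not tested apart, and both stay open.

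Mitotic genes were shifted by 1.25 and 2.60 in PRC1 i2KO 1 and 3 and by 0.083 in PRC1 i2KO 2, and the first pair also had more mitochondrial ribosomal RNA (29.7% and 32.0% of counts against 21.4%). If these libraries held more of every other skin cell type alike, interfollicular markers would follow, but there they lay below their level in PRC1 i2KO 2 by a median of -1.12 (quartiles -1.76 and -0.369, 37 of 40 lower). Fibroblast markers (shifts of 1.07, 1.10 and 1.34 in PRC1 i2KO 1, 2 and 3) differed in the same contrast by a median of -0.0916 (quartiles -0.375 and 0.253, 9 of 14 lower) and upper follicle markers (0.73, 0.53 and 0.95) by 0.268 (quartiles -0.208 and 0.612, 9 of 27 lower), which leaves single types open, although the gates for EpCAM, CD34 and Sca1 should remove them. Whether repression was lost more weakly in PRC1 i2KO 2 stays open, since the 79 tested developmental transcription factors differed there from the other libraries by a median of -0.113 with quartiles of -0.643 and 0.615. A difference in RNA quality or in the hair cycle stage of the sampled skin was not tested and stays open.

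Rnf2 was lower in TPM and not in counts, so its ratio of count to TPM was higher in PRC1 i2KO, by 0.72 (log2), a shift that 2.36% of 10010 protein-coding genes reached. The ratio restates the difference between both units and does not give its cause, and reads over single exons were not analysed here.

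Among Hox genes, 7 of the 8 tested genes of groups 10 to 13 and 5 of the 27 of groups 1 to 9 were higher in every PRC1 i2KO library than in both controls, a split made after the values were seen. The groups also differ in control expression, as 7 of the 8 and 2 of the 27 had a control mean under 1 CPM. Genes silent in control enter the test only when expressed in PRC1 i2KO. The 3 Hox genes of the table that were not tested, with at most 75 counts each, were Hoxa11, Hoxb13 and Hoxc11. All of these belong to groups 10 to 13, so the 8 tested genes leave out the members with few counts. Hoxc13, of groups 10 to 13, was at 37.5 CPM in control and had a log2 fold change of 0.20 (edgeR adjusted p = 0.878). In groups 1 to 9, the genes under 1 CPM in control were Hoxb2 and Hoxd1. Hoxb2 (2.52, adjusted p = 0.292) and Hoxd1, with no control count (adjusted p = 0.435), were higher without passing. In these genes a rise thus went with low control expression, but they are too few to separate it from position.

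Igf2 and Dlk1 are both imprinted, but the other imprinted genes were not called higher as a class. The other 31 tested imprinted genes had a median log2 fold change of 0.0647, with 17 positive (camera p = 0.325, and p = 0.344 with an estimated correlation), and 0 passed edgeR's threshold. At an unadjusted p under 0.05, 5 of the 31 were higher and 0 lower, where 1647 and 778 of all 22181 tested genes were. A rise of some of the 31 is therefore not excluded.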
